A study of Homo sapiens with 9 samples.

How the data were processed

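Gene expression was measured in U-2 OS, a human cell line established from an osteosarcoma, in 9 RNA sequencing libraries. The labels divide them into the wild type (WT) line and 2 clones, 1P and 3.3, whose TDP1 gene carries the H493R change, with 3 libraries per group. Total RNA was taken with TRIzol and made into libraries with a kit that keeps strand information, per the labels' protocols. The series title describes the cells as non-replicating. How that state was reached, how the clones were derived, and whether the libraries of a group came from separate cultures are not given in the sources used here, so p-values measure the spread between these libraries, which may be technical.

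The authors trimmed reads with Trimmomatic, aligned them with HISAT2 to hg38 and used StringTie, per the submitters' processing notes, which give no versions. Each deposited file is a gene abundance table with a coverage, an FPKM and a TPM for 60660 gene IDs, per the file headers. The annotation release is not given in the sources used here. The TPM values of each deposited file sum to 1000000. The deposited coverage is the mean read depth over a gene and the deposited FPKM is that depth scaled to library size. The files hold no read counts, so no count model was used. The highest ratio of coverage to FPKM is the same for many genes of a library and was read as the aligned sequence, 6.68 to 11.2 Gb per library. Read numbers per gene are unknown, and no counting interval is given for any level.

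TPM is a share of a total. Small non-coding RNAs, chiefly the 7SL and 7SK RNAs and their copies, held 48.0% to 77.6% of that total. A library with more of them thus has lower TPM for every other gene. The set was taken by gene type and name. It also holds ribosomal RNAs, mitochondrial ones included, and mitochondrial transfer RNAs. The 7SL and 7SK RNAs and their copies alone held 34.8% (WT replicate 2) to 59.7% (clone 3.3 replicate 1). Entries with the same gene ID were summed. Gene types were taken from GENCODE 29, which types 58429 of the IDs and leaves 2231 without a type. Coordinates are those of the deposited files, on hg38.

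Genes with at least 1 TPM in at least 3 of the 9 libraries were tested, which left 17884. The test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with lmFit, eBayes with a variance trend, one mean per group and all 9 libraries in a single fit. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. A fold change on this scale understates the change of genes with low values. Over all tested genes the median log2 fold change was -0.12 in clone 1P, -0.45 in clone 3.3 and 0.34 for clone 1P minus clone 3.3. Fold changes are therefore printed relative to that median, as relative log2 fold changes, while adjusted p-values belong to the unshifted fit. Beside it, TPM was scaled by median-of-ratios factors, called scaled TPM here (17002 genes tested).

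For 31 gene lists fixed before the data were examined, camera (limma) compared each list with 5 or more measured members against all other genes, with a preset correlation of 0.01 and again with an estimated correlation. The p was adjusted over the lists. The genes of each 10 Mb window with at least 10 tested genes were averaged per library. Each library was then centred on its median over windows, and limma was run on the windows. A window was called at an adjusted p under 0.05 and a shift of at least 0.3. Genes with a span of at least 100 kb were compared with the other genes in each library, with exact two-sided permutation tests.

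The genes named in the text were chosen by a rule fixed before the data were examined: the 10 largest increases and 10 largest decreases of each clone, the same for both clones by the smaller of the 2 changes, 5 in each direction between the clones, up to 4 called members of each list, and TDP1. Except for list members and TDP1, the rule required a mean of at least 5 TPM in a group and all 3 libraries of one group on the same side of all 3 of the other. Genes without a symbol of their own were left out. Names outside the rule are said to be so. Before use, the fit was tested on values simulated with the real mean and spread of each gene, drawn independently for each gene and library. Changed genes were taken from those with a mean of at least 2 on the log2(TPM + 1) scale. For clone 1P against WT, 15 of 68 genes changed by 1 on the log2 scale were recovered. Of those changed by 2, 39 of 66 were, and of those changed by 4, 51 of 66, with 10 false calls among 17884 genes. Independent draws hold no structure shared by libraries, so these false calls do not bound those in the real data. The spread between libraries of a group thus hides many changes.

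Replicate numbers come from the labels, which do not say what they mark. Deviations from the group means, on scaled TPM, correlated between WT and clone 1P libraries of the same number at 0.83, 0.52 and 0.78. Same-numbered libraries of these 2 groups thus deviated alike. Replicate 1 stood apart in both groups, and correlations between different numbers are not given, so pairing of the other numbers is not shown. The numbers do not pair clone 3.3, whose replicate 2 did not deviate with the other libraries of that number. A fit of the WT and clone 1P libraries alone with the replicate number as a block was therefore added, after the unpaired results were seen, and is called the replicate block fit. The block was picked because these same values deviated alike, so calls found only in that fit are not separate support.

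Alternatives covered the pseudocount, the filter, FPKM, scaled and quantile-normalised values, the replicate number as a block, library weights, the variance trend, the fold size, the libraries in the fit and each library left out in turn. The comparison of clones used the shared WT libraries, so unchanged groups were also simulated in 100 draws. All 9 libraries, WT included, were redrawn from the residuals around the mean of each gene. Both simulated clones were set against the same simulated WT libraries. Each library was drawn on its own, so any link between same-numbered libraries was not kept. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.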

Results

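The series asks how loss of TDP1 function changes transcription in U-2 OS cells that are not replicating. TDP1, tyrosyl-DNA phosphodiesterase 1, removes topoisomerase 1 trapped on DNA, and the H493R change is the one known from spinocerebellar ataxia with axonal neuropathy. RNA levels were available as TPM for 3 WT libraries, 3 libraries of mutant clone 1P and 3 of mutant clone 3.3. Aligned sequence ranged from 6.68 Gb in clone 3.3 replicate 3 to 11.2 Gb in WT replicate 1.

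The libraries differed in the share of TPM held by the small non-coding RNAs, as defined above. Such RNAs held 62.9%, 48.0% and 52.2% of TPM in WT replicates 1, 2 and 3. The shares were 69.1%, 52.8% and 52.9% in clone 1P and 77.6%, 64.7% and 58.5% in clone 3.3. The replicate 1 library had the highest share of its group in all 3 groups. In a principal component analysis of scaled TPM the first component held 56.8% of the variance and set the 3 replicate 1 libraries and clone 3.3 replicate 2 apart from the other 5 libraries. The second, with 27.1%, separated WT from both clones. Small RNAs share the TPM total with all other genes, so fold changes below are relative to the median gene.

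**Figure D1:**
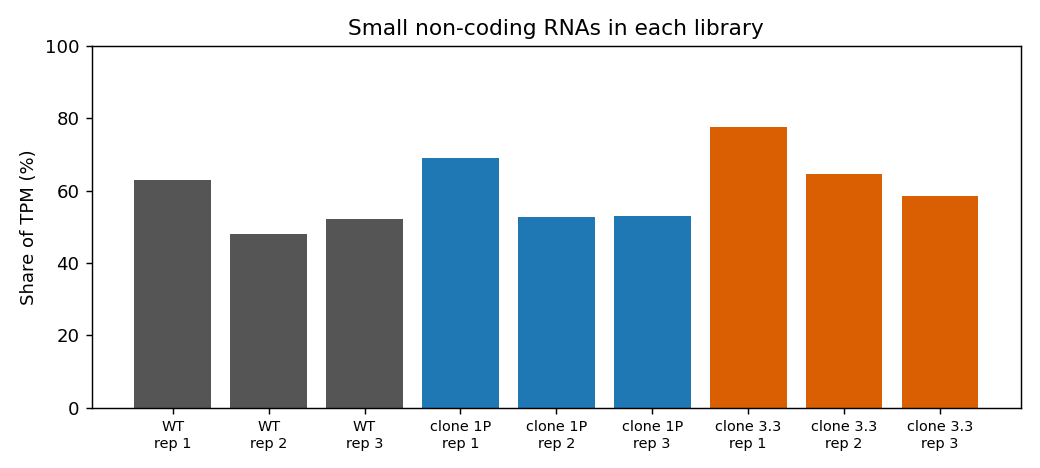
Bars give the share of TPM, in percent, held by small non-coding RNAs in each of the 9 libraries, coloured by group. The share runs from 48.0% in WT replicate 2 to 77.6% in clone 3.3 replicate 1, and the replicate 1 library is the highest of each group.

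TDP1 mRNA was lower in both clones. TDP1 (ENSG00000042088.14, hg38 chromosome 14, 89954939 to 90044764) averaged 14.4 TPM ± 2.92 (SD, n = 3) in WT. It averaged 5.2 TPM ± 1.38 (SD, n = 3) in clone 1P and 4.32 TPM ± 2.41 (SD, n = 3) in clone 3.3, and each mutant library lay below all WT libraries. The relative log2 fold change was -1.20 in clone 1P and -1.17 in clone 3.3, each with a standard error of 0.38. In limma the fall passed the threshold in clone 3.3 (adjusted p = 0.0292) and not in clone 1P (adjusted p = 0.0828); on scaled TPM it passed in both (adjusted p = 0.0113 and 0.0115). In clone 1P it also passed in the replicate block fit (adjusted p = 0.00149). In clone 3.3 the call on TPM was lost when any 1 library was left out, other than clone 1P replicate 1 or clone 3.3 replicate 3. The clones did not differ detectably from each other (relative log2 difference -0.03, adjusted p = 0.782). A missense change need not alter the mRNA level, so this level does not check the labels, and genes next to TDP1 on its distal side were lower too, as given with the chromosome windows.

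**Figure D2:**
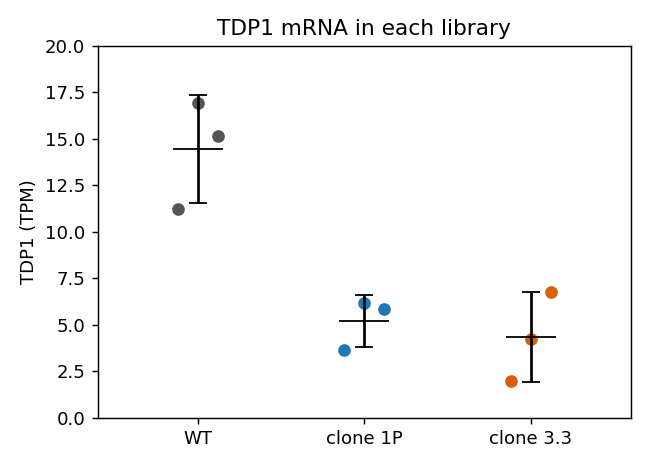
TDP1 mRNA in TPM for each library (points), with the mean and SD of each group of 3 (bar and whiskers). WT libraries lie between 11.2 and 16.9 TPM and the 6 mutant libraries between 1.96 and 6.78 TPM.

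Clone 1P was compared with WT to ask which transcripts differ in one mutant clone. Several of the largest increases were in genes with little RNA in WT. TGM2, a transglutaminase that cross-links proteins, rose from 2.80 TPM ± 1.53 to 243 TPM ± 51.8 (SD, n = 3 each). F2R, the thrombin receptor, rose from 0.245 TPM ± 0.297 to 53.7 TPM ± 20, and the keratin KRT17 from 30.8 TPM ± 11.1 to 769 TPM ± 69.5. The annexin ANXA10 rose from 0.0904 TPM ± 0.0870 to 19.1 TPM ± 10.3 (relative log2 fold change 4.15 ± 0.67 SE, adjusted p = 0.01). The long non-coding RNA LINC02474 rose to 165 TPM ± 64.2 from 0.951 TPM ± 0.834. The largest decreases included the histone gene H3C6, which fell from 56.4 TPM ± 8.77 to 0.630 TPM ± 0.345, and MGP, the matrix Gla protein that restrains calcification, which fell from 26.1 TPM ± 16 to 0.0847 TPM ± 0.0488. The cancer-testis antigen MAGEA10 fell from 21.5 TPM ± 7.64 to 0.0630 TPM ± 0.0382. RNVU1-6, a variant U1 small nuclear RNA with near-identical copies among which reads may be split, fell from 23.1 TPM ± 8.32 to 1.31 TPM ± 2.18. Adjusted p-values of these genes lay between 0.000103 for TGM2 and 0.0344 for RNVU1-6. In all, limma called 1325 of 17884 genes, 550 higher and 775 lower. On scaled TPM it called 516 higher and 503 lower, with 299 of the 550 and 323 of the 775 called again and 0 in the opposite direction. The replicate block fit called 5839, 1979 higher and 3860 lower, and on scaled TPM 2734 higher and 2568 lower. Leaving out any 1 of the 6 WT and clone 1P libraries lowered the count to between 608 (WT replicate 3) and 881 (WT replicate 1).

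Clone 3.3 was compared with WT in the same way. The insulin-like growth factor binding protein IGFBP7 rose from 3.59 TPM ± 0.432 to 84.8 TPM ± 34.1 (SD, n = 3 each; relative log2 fold change 4.60 ± 0.37 SE, adjusted p = 0.000618). H4C4, a replication-dependent histone gene, rose from 0.973 TPM ± 0.388 to 130 TPM ± 51.0, and the vesicle priming gene UNC13D from 2.94 TPM ± 1.70 to 70.2 TPM ± 18.6. ID1, an inhibitor of basic helix-loop-helix transcription factors, fell from 925 TPM ± 375 to 72.5 TPM ± 36.8 (relative log2 fold change -3.29 ± 0.45 SE, adjusted p = 0.00214). The cancer-testis antigen MAGEA4 fell from 249 TPM ± 65.8 to 11.8 TPM ± 4.08, and PALM3 from 12.5 TPM ± 2.61 to 0.0501 TPM ± 0.0437. limma called 2146 genes, 501 higher and 1645 lower. On scaled TPM the split was 760 higher and 611 lower, with 359 of the 501 and 477 of the 1645 called again. Scaling sets the median gene near 0, so it cannot show where the excess of lower genes comes from. On FPKM 699 were higher and 1212 lower. With small non-coding RNAs left out and TPM rescaled, which sets no median, 1093 of the 22125 genes then kept were higher and 1088 lower, so the excess depends on counting those RNAs in the total. Without WT replicate 2, WT replicate 3 or clone 3.3 replicate 2 the count was 969, 951 and 1416.

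Of the 1325 genes called in clone 1P, 1039 were called the same way in clone 3.3. The 10 largest shared increases were H4C4, LINC02474, F2R, TGM2, LINC02582, UNC13D, LINC01029, ALPP, KRT17 and DYSF. ALPP, the placental alkaline phosphatase, went from 0.326 TPM ± 0.303 in WT to 28.2 TPM ± 3.81 in clone 1P and 21.6 TPM ± 7.99 in clone 3.3 (SD, n = 3 each). DYSF, which encodes the membrane repair protein dysferlin, went from 0.455 TPM ± 0.101 to 16.2 TPM ± 3.02 and 18.5 TPM ± 4.13. The 10 largest shared decreases were H3C6, MGP, MAGEA10, FXYD7, GPAT2, PRUNE2, GLUL, ELN, MAP1A and MFAP4. GLUL, glutamine synthetase, went from 15.1 TPM ± 3.27 to 0.488 TPM ± 0.0752 and 0.0216 TPM ± 0.0375. The elastin gene ELN went from 12.3 TPM ± 3.62 to 0.293 TPM ± 0.0539 and 0.0549 TPM ± 0.0746, and FXYD7, a regulator of the sodium pump, from 26.4 TPM ± 2.25 to 0.487 TPM ± 0.128 and 0.474 TPM ± 0.0548. The 20 genes were also called in both clones on scaled TPM. Of the 1039 shared genes 342 were higher and 697 lower. Simulated unchanged groups, with both clones set against the same simulated WT libraries, gave means of 0.15 and 11.57, with highest values of 15 and 1157. Independent lists would share 15.4 and 71.3. On scaled TPM the shared counts were 386 and 394, with 0 and 0 in the simulation and 23.1 and 18.1 for independent lists. Across genes the fold changes of the clones had a covariance of 0.386, against a simulated mean of 0.0671 and highest value of 0.565, and a correlation of 0.85, against 0.38 and 0.99. Simulated unchanged groups that share WT libraries can thus reach the observed covariance and correlation, in draws that keep no link between same-numbered libraries. The 3 WT libraries cannot be split into parts of at least 2, so part of the overlap may come from the shared controls. For shared genes and for the lists below, an effect of the mutation is not separated from a shared origin of the clones. The shared count was 515 without WT replicate 2, 466 without WT replicate 3, and 666, 527 and 534 without clone 1P replicates 1, 2 and 3.

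Among the gene lists, p53 target genes stood higher in both clones. In each clone 8 of 36 measured members rose and 1 fell. GDF15, a secreted stress factor, rose from 6.30 TPM ± 2.45 to 48.2 TPM ± 11.1 in clone 1P and 42.2 TPM ± 28.3 in clone 3.3 (SD, n = 3 each). FDXR, mitochondrial ferredoxin reductase, rose from 41.7 TPM ± 4.30 to 96.8 TPM ± 10.7 and 73.8 TPM ± 15.1; on scaled TPM it missed the threshold (adjusted p = 0.12 and 0.0845). The cell cycle inhibitor CDKN1A was 132 TPM ± 16 in WT and 171 TPM ± 13.9 in clone 1P (adjusted p = 0.152; 0.033 in the replicate block fit), and rose to 209 TPM ± 2.89 in clone 3.3 (adjusted p = 0.0149; 0.0881 on scaled TPM). PGF was the member that fell. On scaled TPM 7 members rose and 1 fell in clone 1P, and 10 rose and 0 fell in clone 3.3. Adjusted over the list alone, 13 rose and 3 fell in clone 1P, and 8 rose and 1 fell in clone 3.3. The list median relative to all genes was 0.84 and 0.76 (camera adjusted p = 4.26e-07 and 2.83e-07). With an estimated correlation the call was lost (adjusted p = 0.997 and 0.806 with an estimated correlation).

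Part of the extracellular matrix and collagen genes rose. In clone 1P 11 of 33 rose and 3 fell, and in clone 3.3 8 rose and 3 fell; over the list alone 18 rose and 4 fell, and 13 rose and 3 fell. COL6A3 rose from 3.53 TPM ± 0.474 to 51.0 TPM ± 6.46 and 36.8 TPM ± 13.8, and COL4A2, a basement membrane collagen, from 33.3 TPM ± 3.89 to 159 TPM ± 10.6 and 156 TPM ± 22.0. The elastin gene ELN was among those that fell in both. List medians were 0.99 and 0.94 relative to all genes (camera adjusted p = 4.26e-07 and 8.44e-07; 0.997 and 0.806 as adjusted p with an estimated correlation). Senescence-associated secreted factors stood higher, with 8 of 25 rising and 2 falling in clone 1P and 6 rising and 2 falling in clone 3.3 (camera adjusted p = 0.00201 and 3.05e-05; adjusted p = 0.997 and 0.806 with an estimated correlation). Over that list alone, 8 rose and 3 fell, and 8 rose and 4 fell. Its risers included TIMP1, an inhibitor of metalloproteinases, at 306 TPM ± 18 in WT, 804 TPM ± 44.9 in clone 1P and 732 TPM ± 43.1 in clone 3.3. Of 25 NF-kB and TNF response genes 7 rose in clone 1P and 1 in clone 3.3, with 11 rising and 1 falling and 0 and 0 over the list alone (camera adjusted p = 3.13e-06 and 0.000960; adjusted p = 0.226 and 0.770 with an estimated correlation). Of 14 osteoblast genes 2 rose in each clone, with 2 and 2 over the list alone. BMP4, a bone morphogenetic protein, rose from 6.40 TPM ± 3.10 to 57.0 TPM ± 11.7 and 45.9 TPM ± 16.6 (list adjusted p = 0.0274 and 0.0344; adjusted p = 0.997 and 0.933 with an estimated correlation).

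Epithelial genes, listed as markers of another cell type, moved with both clones. Of 11 measured members 4 rose and 0 fell in each clone, and over the list alone 4 rose and 0 fell, and 6 rose and 1 fell. KRT18 rose from 94.1 TPM ± 7.63 to 340 TPM ± 13.9 and 455 TPM ± 60.9, KRT8 from 173 TPM ± 45.0 to 400 TPM ± 38.3 and 573 TPM ± 125, and the tight junction gene CLDN4 from 1.92 TPM ± 0.491 to 16.6 TPM ± 3.91 and 14.2 TPM ± 2.90 (camera adjusted p = 5.22e-05 and 1.38e-08; adjusted p = 0.226 and 0.0820 with an estimated correlation). On scaled TPM the rise of KRT8 in clone 1P missed the threshold (adjusted p = 0.132).

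Cholesterol genes stood lower. Of 29 measured members 4 fell in clone 1P and 16 in clone 3.3, with 4 and 22 over the list alone and none higher. MVD, an enzyme of the mevalonate pathway, fell from 106 TPM ± 12.6 to 26.3 TPM ± 1.70 and 22.7 TPM ± 5.11. On scaled TPM 2 and 4 members fell, and MVD missed the threshold in clone 3.3 (adjusted p = 0.0639). The list median relative to all genes was -0.49 and -0.69 (camera adjusted p = 0.000146 and 8.44e-07; adjusted p = 0.997 and 0.806 with an estimated correlation). S-phase genes fell in 3 and 6 of 42 cases, with 6 and 8 over the list alone. On scaled TPM 1 rose and 0 fell in clone 1P, and 0 rose and 1 fell in clone 3.3. Thymidine kinase TK1 went from 330 TPM ± 35.5 to 114 TPM ± 17.2 and 128 TPM ± 36.1, and missed the threshold on scaled TPM (adjusted p = 0.0736 and 0.28). The S-phase list was called in both clones (camera adjusted p = 0.0179 and 0.00262; adjusted p = 0.997 and 0.933 with an estimated correlation). The mitosis list was not (adjusted p = 0.124 and 0.0779), but was on scaled TPM (adjusted p = 0.00228 and 0.000223), where an estimated correlation again left 0 lists. In clone 1P the replicate block fit called it lower (adjusted p = 0.000251; adjusted p = 0.913 with an estimated correlation). Mitosis genes were also lower in the replicate 1 library of each group than in the others, and clone 3.3 holds 2 of the 4 libraries that stand apart. Replication-dependent histones were called lower (camera adjusted p = 0.0274 and 0.00203) with 3 and 12 of 40 falling and H4C4 rising, and not on scaled TPM, where 3 and 2 fell (adjusted p = 0.202 and 0.326) or, in clone 1P, in the replicate block fit (adjusted p = 0.0634). Oxidative phosphorylation genes were called lower (adjusted p = 0.0274 and 0.000215), with 4 and 8 of 53 falling. On scaled TPM 0 and 1 fell and the adjusted p was 0.0782 and 0.0177. NRF2 target genes were called lower (adjusted p = 0.00953 and 0.00122), with 1 and 7 of 25 falling, and 0 and 10 over the list alone. On scaled TPM 5 and 5 fell. HMOX1, heme oxygenase and the only member called in clone 1P on TPM, fell from 62.8 TPM ± 18.3 to 20.4 TPM ± 6.26 and 12 TPM ± 4.39. With an estimated correlation the histone, oxidative phosphorylation and NRF2 lists all had adjusted p = 0.997 in clone 1P and 0.933 in clone 3.3.

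In clone 3.3 ribosome biogenesis genes were called lower, with 0 of 40 rising and 3 falling (adjusted p = 0.0289), and on scaled TPM 0 fell (adjusted p = 0.0664). Immediate early genes were called higher, although 2 of 27 rose and 5 fell (adjusted p = 0.0459), and on scaled TPM with 3 rising and 0 falling (adjusted p = 0.0032). Small nuclear RNAs were called higher, with 3 of 20 rising and 3 falling (adjusted p = 0.0144), and on scaled TPM 0 rose and 1 fell (adjusted p = 0.391). With an estimated correlation the adjusted p of these 3 lists was 0.933, 0.933 and 0.806. In clone 1P immediate early genes had an adjusted p of 0.0516, and 0.0344 on scaled TPM. The other lists were called in neither clone on TPM. On scaled TPM cytosolic ribosomal proteins were called higher in clone 1P (adjusted p = 0.0182) and quiescence genes in clone 3.3 (adjusted p = 0.0413), and 0 lists were called there with an estimated correlation. Repair genes were among them: of 33 TOP1 lesion and single-strand break repair genes 0 changed in clone 1P and 1, XRCC1, fell in clone 3.3 (list adjusted p = 0.987 and 0.442), and of 40 double-strand break repair genes 1, XRCC3, fell in each (list adjusted p = 0.343 and 0.319). On scaled TPM XRCC1 missed the threshold in clone 3.3 (adjusted p = 0.901) and XRCC3 in both clones (adjusted p = 0.115 and 0.134). In the replicate block fit 4 and 10 members of these 2 lists fell in clone 1P, XRCC1 among them (adjusted p = 0.0148), and neither list was called (adjusted p = 0.72 and 0.0651). On scaled TPM that fit had 2 rising and 1 falling in the first list, and 1 rising and 5 falling in the second. Of 25 spinocerebellar ataxia genes 2 and 4 fell (list adjusted p = 0.987 and 0.376), and on scaled TPM 1 rose and 1 fell, and 0 rose and 2 fell. Of 5 measured haematopoietic markers 1 rose and 2 fell in clone 1P, and 0 rose and 2 fell in clone 3.3. Of 19 neuronal genes 2 rose and 4 fell, and 1 rose and 5 fell; TUBB3, a neuronal tubulin, fell from 225 TPM ± 15 to 71.5 TPM ± 9.42 and 54.8 TPM ± 24.3. The replicate block fit called more members in clone 1P: 23 p53 targets rose and 3 fell, 21 matrix genes rose and 7 fell, 0 cholesterol genes rose and 21 fell, and 2 S-phase genes rose and 22 fell. On scaled TPM that fit had 25 and 2, 21 and 6, 0 and 12, and 2 and 17. FDXR, KRT8, TK1 and XRCC3, which missed the threshold in clone 1P on scaled TPM, passed it there in that fit (adjusted p = 0.00054, 0.00185, 0.000587 and 0.00219). The block was chosen on these same data, so this does not restore their calls. On TPM the replicate block fit called 11 lists, and 0 with an estimated correlation.

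**Figure D3:**
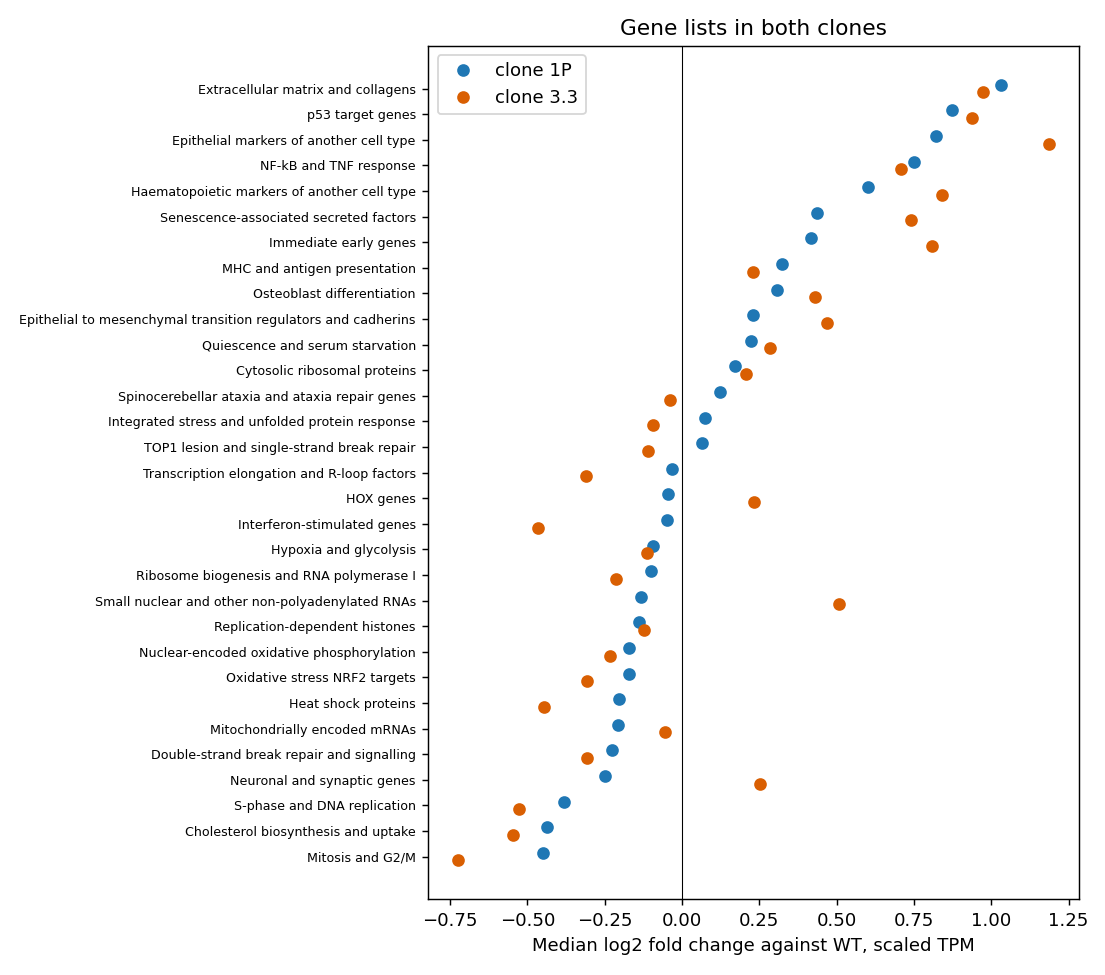
Median log2 fold change against WT on scaled TPM for the measured members of each of the 31 gene lists, with 1 point per clone. Extracellular matrix, p53 target and epithelial lists lie highest in both clones, and the mitosis list lies lowest at -0.45 in clone 1P and -0.72 in clone 3.3.

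The clones were compared with each other to ask whether their differences from WT depend on the clone. The cancer-testis antigen MAGEA4 was higher in clone 1P at 69.3 TPM ± 11.4 against 11.8 TPM ± 4.08 in clone 3.3 (SD, n = 3 each). YBX2, a germ cell RNA-binding protein, was 16.9 TPM ± 1.65 against 2.20 TPM ± 0.225, and the kinesin KIF1A 8.88 TPM ± 2.29 against 1.12 TPM ± 0.556. The adhesion molecule ICAM1 was 8.37 TPM ± 2.05 against 1.41 TPM ± 0.556. Genes higher in clone 3.3 included SMOC1 at 12.2 TPM ± 1.68 against 2.72 TPM ± 0.622, and AGRN, agrin, at 660 TPM ± 34.8 against 213 TPM ± 43.4. AGRN, CPTP and FAAP20 lie within the first few megabases of chromosome 1. limma called 37 genes, 26 higher and 11 lower in clone 1P, and 9 on scaled TPM, 5 higher and 4 lower. Of the genes named here, MAGEA4 was called on scaled TPM as well (adjusted p = 0.0317). Leaving out any 1 of the 9 libraries left between 1 (without clone 1P replicate 2) and 10 genes (without clone 1P replicate 1).

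Long genes were examined because topoisomerase 1 activity matters most for their transcription. The 2924 genes of at least 100 kb, measured against 14960 others, showed no detectable shift, and with this spread between libraries a small shift is not excluded. The long-gene value was 0.0039 ± 0.225 (SD, n = 3) in WT, 0.056 ± 0.285 in clone 1P and -0.033 ± 0.336 in clone 3.3, on the log2 scale. The 6 mutant libraries differed from the 3 WT libraries by 0.00755 (exact two-sided permutation p = 0.988). Each clone against WT gave exact p = 0.8 and 0.9, where 3 against 3 libraries cannot give less than 0.1. The value followed the library: it was -0.25, -0.27 and -0.29 in the replicate 1 libraries and -0.15 in clone 3.3 replicate 2. It was positive in the other 5, at 0.092 and 0.17 in WT, 0.16 and 0.28 in clone 1P and 0.35 in clone 3.3. The permutation tests do not take this library structure into account, nor that the 6 mutant libraries come from 2 clones.

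Neighbouring genes moved together in some chromosome regions. Of 300 windows of 10 Mb, 23 were called in clone 1P, 23 in clone 3.3 and 18 in both with the same sign, 8 higher and 10 lower. The lowest was chromosome 9 from 10 to 20 Mb, with a shift of -1.76 ± 0.16 (SE) in clone 1P and -1.74 ± 0.16 in clone 3.3, and its neighbours on the short arm shifted by -0.87 and -0.88 (0 to 10 Mb) and by -0.71 and -0.73 (20 to 30 Mb). Genes there, chosen after their values were seen, included RPS6, a ribosomal protein gene at 1370 TPM ± 461 in WT, 281 TPM ± 143 in clone 1P and 208 TPM ± 131 in clone 3.3. PLIN2, a lipid droplet protein, was 120 TPM ± 12.8, 15.3 TPM ± 2.96 and 10.4 TPM ± 2.19. Chromosome 14 from 90 to 100 Mb, which begins beside TDP1, shifted by -0.85 ± 0.12 and -0.76 ± 0.12. Of the tested genes within 2 Mb of TDP1, the 14 before it had a median relative log2 fold change of 0.064 and 0.025, and the 9 after it of -1.09 and -1.30. Chromosome 18 was higher from 0 to 20 Mb and lower from 50 to 70 Mb in both clones. Between the clones 0 windows were called in limma (7 at an unadjusted p under 0.05). Leaving out WT replicate 2 left 3 windows in each clone, and leaving out WT replicate 3 left 4 and 7. In clone 1P the count was 3 without clone 1P replicate 2 and 7 without replicate 3, and in clone 3.3 it was 7 without clone 3.3 replicate 1 and 3 without replicate 2. The 18 shared windows held 67 of the 1039 genes called the same way in both clones, and 809 of the 17884 tested genes.

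**Figure D4:**
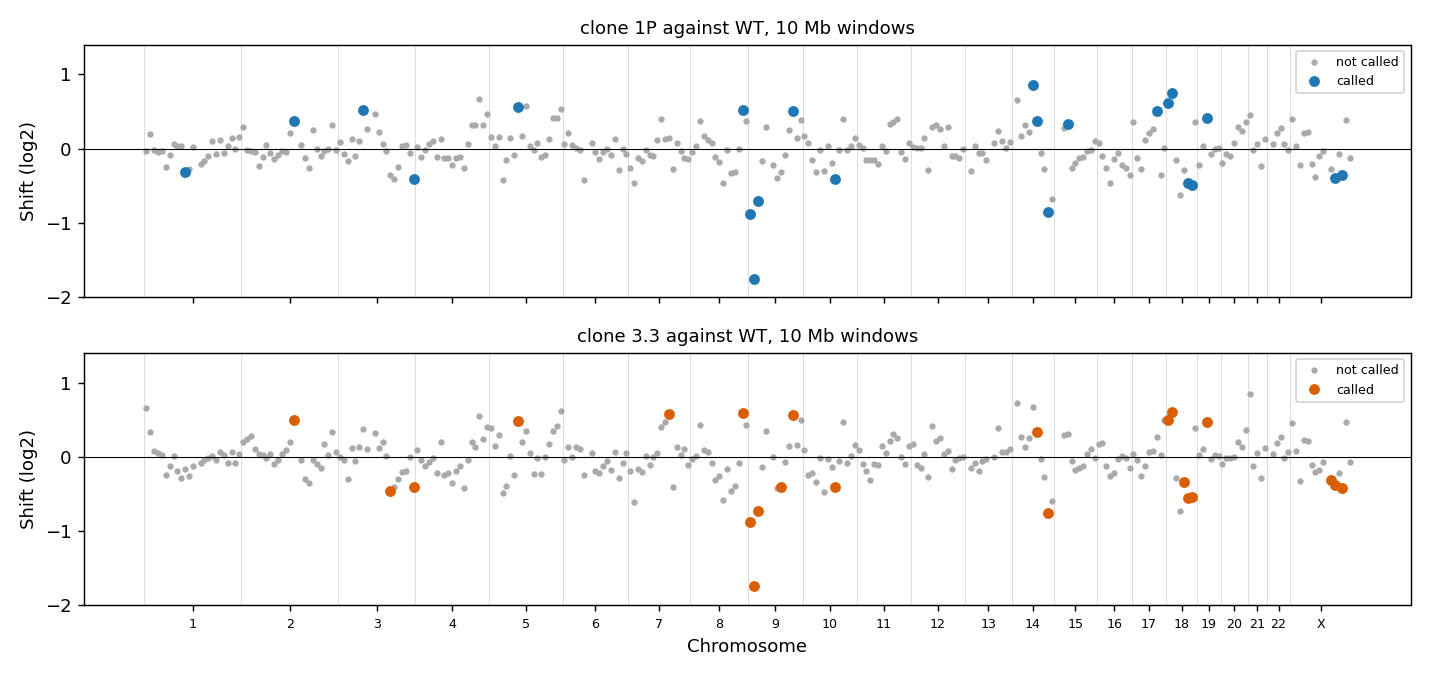
Mean shift of the tested genes of each 10 Mb window against WT (log2, centred on the median window) along the chromosomes, for clone 1P (top) and clone 3.3 (bottom), with called windows in colour. The lowest window in both clones is chromosome 9 from 10 to 20 Mb, at -1.76 and -1.74.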

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

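Tests of the 3 patterns weighed at the end were chosen after the results were seen, except that on transcript length. These results differed between the 2 clones under the same contrast, by the test of the difference itself in the fit of all 9 libraries. As log2 fold changes of clone 1P minus clone 3.3, where the median gene lies at 0.34, they were MAGEA4 (2.5), YBX2 (2.48), KIF1A (2.23), BIRC7 (2.15), ICAM1 (1.97), ALDOC (1.62), KRT75 (-1.90), SMOC1 (-1.83), AGRN (-1.65), FAAP20 (-1.23) and CPTP (-1.23). The camera adjusted p of lists differing between the clones was 0.000125 for small nuclear RNAs, 0.00062 for cholesterol genes, 0.00268 for NF-kB genes, 0.00283 for epithelial markers, 0.00842 for the integrated stress response, 0.00969 for ribosome biogenesis, 0.0125 for oxidative phosphorylation, 0.0193 for cytosolic ribosomal proteins, 0.0193 for transcription elongation factors, 0.0219 for hypoxia genes and 0.0322 for histones. On scaled TPM the NF-kB, integrated stress, oxidative phosphorylation, cytosolic ribosomal protein, hypoxia and histone lists lost the call (camera adjusted p from 0.23 to 0.784). With an estimated correlation 0 lists differed. Groups of 3 libraries were too small for a search for single outlying libraries.

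Other splits of the libraries bear on each count. For clone 1P against WT the real split called 1325 genes and the highest of the other 9 splits called 1, and for clone 3.3 against WT 2146 and 0. For windows the values were 23 and 0 in clone 1P and 23 and 67 in clone 3.3. For clone 1P, 4 of the 10 splits part all 3 same-numbered pairs, and the highest of the 3 others called 1 gene. With 10 splits a share under 0.05 cannot be reached, so these comparisons cannot decide. Between the clones 37 genes were called and another split called 8122, with 164 windows against 0. That split put clone 1P replicate 1 and clone 3.3 replicates 1 and 2 on one side, which points to a structure of the libraries larger than the clone difference. It is the same set that the small non-coding share and the first principal component set apart. For lists, 11, 14 and 11 were called by the real splits, and 16, 18 and 16 by the highest of the others. As many lists as the real split were called by 6, 3 and 3 of the 10 splits, the real one included, and as many genes by 1, 1 and 2. As many windows were called by 1, 2 and 10. For genes changed the same way in both clones, 2 of 100 splits drawn from 840 gave 1039 or more, the real one included. The highest of the others, 2868, put the 3 replicate 1 libraries in one group. Library structure can thus exceed the real count, and splits that cut across it may call few genes whatever the cause. The share of splits therefore does not decide.

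Windows shifted the same way in both clones were weighed first. On scaled TPM with the small non-coding share as a term, 18 of the 18 windows kept a shift of at least 0.3 in both clones, which argues against that share as the cause. In the median of these windows 79.0% of genes lay on the side of the shift in both clones, against 49.8% in other windows. Most genes of the median window thus moved with the shift. The windows were chosen for that shift, so an excess is built in, and fewer windows were called by medians, as given further on. A few strong genes are therefore not excluded for every window. Shared windows lay side by side with the same sign in 4 cases, against a mean of 0.442 for 100000 random placements (permutation p = 0.00068). Random placement treats windows as interchangeable, so this p-value does not tell copy number from another cause that acts along a chromosome. A candidate explanation, as a hypothesis, is a copy number difference between the WT line and both clones, and the adjacency is consistent with it. DNA copy number was not analysed here, and nothing tested here separates a shared origin of the clones from an effect of the mutation.

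The small non-coding share of libraries of one group was weighed next. Across 12564 protein-coding genes, the replicate 1 library minus the others had a Spearman correlation with transcript length of -0.22 in WT, -0.19 in clone 1P and -0.188 in clone 3.3; genes are not independent replicates. The value foreseen for fewer intact long transcripts, below -0.2 in all groups, was met in WT alone. In clone 3.3 the others include replicate 2, itself a library with a high share. Clone 3.3 replicate 2 minus replicate 3, a comparison of single libraries, gave -0.27. The explanation by fewer intact transcripts may hold and cannot be told apart from none with these files, which carry no measure of RNA integrity. The 40 mitosis genes were lower in each replicate 1 library, by medians of -0.39, -1.18 and -1.12. These medians lay at percentile 0 of 10000 random lists matched on expression and transcript length, as fewer dividing cells in those libraries could give. Genes of the random lists were drawn singly, whereas mitosis genes move together, with an estimated correlation of 0.86. The percentile therefore does not measure how unusual the fall is. The labels give no batch or culture state per library.

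For lower TDP1, weighed last, the TPM total is argued against, since on scaled TPM the weaker of the 2 falls was still -1.11 and past the threshold. For a lower block around TDP1, the median relative log2 fold change of 23 neighbours within 2 Mb was -0.56 in clone 1P and -0.258 in clone 3.3. The value in clone 1P passes the bound set for a lower block and that in clone 3.3 lies between the bounds for and against it. Genes before TDP1 lay near the median gene and genes after it below. A block edge at TDP1 may therefore account for the level and cannot be told apart from an effect of the edited gene itself, which the design does not separate.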

How the results depend on the processing

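Several alternatives were chosen after seeing the data: scaled TPM with a block, the block for WT and clone 1P alone, with the small non-coding share as a term, with the fold condition or with an estimated correlation, small RNAs left out, libraries left out as a set, and scaled or protein-coding values for long genes and windows. Where a value moved, the cause was not tested unless said. Counts are given for clone 1P, clone 3.3, both clones and the clone difference in that order. The replicate block gave 3665, 8209, 2959 and 619 genes and, on scaled TPM, 4102, 5901, 3118 and 583. With clone 3.3 the numbers do not pair: deviations of clone 3.3 correlated with WT and clone 1P at 0.79 and 0.87 for number 1 and 0.79 and 0.86 for number 3, but at -0.17 and -0.092 for number 2, so not every library went with its own number. For WT and clone 1P alone the replicate block gave 5839, and 5302 on scaled TPM, TDP1 passing in both (-1.32 and -1.16), with 11 and 12 lists called. Histones lost their call and mitosis genes gained one, and it changed no other list call on TPM. Array weights, whose estimation did not converge, gave 4848, 13287, 3851 and 12072. The share as a term gave 4578, 5292, 3216 and 414. Leaving out replicate 1 and clone 3.3 replicate 2 on scaled TPM gave 5160, 4513, 3219 and 94. A 2-fold condition on scaled TPM gave 877, 1163, 654 and 9, and on TPM 1405 in clone 3.3. Scaled TPM gave 1371 in clone 3.3 and 9 between clones. Fits of 2 groups gave 1012 in clone 3.3 and 1 between clones, and 6 mutant against 3 WT libraries 1779. Between clones no filter gave 8, quantile normalization 16, and leaving out replicate 1 gave 4, or 12 on scaled TPM. With 1 library left out at a time, the ranges were 608 to 1604, 951 to 1984, 466 to 1043 and 1 to 10. The other alternatives stayed within 1.5 times these counts.

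Values of TDP1 here are not relative to the median gene, and on the original settings are -1.32 in clone 1P and -1.63 in clone 3.3. TDP1 in clone 1P passed the threshold at -1.20 on FPKM, -1.16 on scaled TPM, with or without the block, -1.17 on quantiles, -1.32 with the block and in the fit of 2 groups, -1.24 with array weights, -1.28 without small RNAs, -1.16 with the share as a term, -1.28 without replicate 1, and -1.13 on scaled TPM without replicate 1, with or without clone 3.3 replicate 2. Of single libraries left out, only clone 3.3 replicate 1 brought it past the threshold (-1.32, adjusted p = 0.031). In clone 3.3 it missed the threshold, at an unchanged -1.63, with no filter and in the fit of 2 groups. Leaving out 1 library gave -1.48 to -1.13 and -1.96 to -1.26. With an estimated correlation, 0 lists were called in each comparison, on TPM and scaled TPM. Lists differing between clones were 5 on scaled TPM, 5 there with the block, 3 with a filter of 5 TPM, 4 without small RNAs, 6 on scaled TPM without replicate 1, 6 with the share, and 3 to 15 with 1 library left out. Histones reversed in clone 3.3 (adjusted p = 0.941, scaled TPM without replicate 1) and between clones (on scaled TPM 0.784, 0.468 with the block, 0.451 without replicate 1 and 0.936 with an estimated correlation). With 1 library left out, their adjusted p between clones on TPM ran from 4.66e-09 without clone 3.3 replicate 2 to 0.592, reversed, without clone 3.3 replicate 3. Small nuclear RNAs reversed with the share (0.47 in clone 3.3, 0.815 between clones), and hypoxia genes between clones (0.91 with the block, 0.999 without replicate 1, both scaled).

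Long genes, never past the threshold, changed sign at 50 kb (-0.00800 in clone 1P, -0.0592 in all mutants), at 200 kb (0.0357 in clone 3.3), in protein-coding genes (0.0181 in clone 3.3), on scaled TPM (-0.00586, all mutants) and without replicate 1 (-0.000566, all mutants). With 1 library left out they ran from -0.0801 to 0.206 in clone 1P, -0.227 to 0.0784 in clone 3.3 and -0.125 to 0.0881 over all mutants. Windows called in clone 1P and clone 3.3 were 52 and 52 at 5 Mb, 9 and 12 at 20 Mb, 8 and 13 by medians, and 5 in clone 1P on scaled TPM without replicate 1. With 1 library left out they were 3 to 25 and 3 to 30.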

Other observations

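The chromosome 9 block was chosen after the result was seen. Further genes changed in both clones outside the groups described so far. DYRK1B, a kinase of quiescent cells, rose from 0.977 TPM ± 0.431 in WT to 17.2 TPM ± 2.82 in clone 1P and 13 TPM ± 0.967 in clone 3.3 (SD, n = 3 each), though its quiescence list was called in neither clone on TPM (adjusted p = 0.0413 in clone 3.3 on scaled TPM). The glucose transporter SLC2A1 rose from 26.3 TPM ± 3.45 to 117 TPM ± 24.2 and 85.3 TPM ± 12.2. In its hypoxia and glycolysis list 1 of 33 rose and 2 fell in clone 1P, and 1 rose and 10 fell in clone 3.3. On scaled TPM 1 rose and 0 fell, and 1 rose and 1 fell. That list was called in neither clone (camera adjusted p = 0.554 and 0.104 on TPM). HOXD10, a homeobox gene of limb patterning, fell from 13.3 TPM ± 3.89 to 1.4 TPM ± 0.535 and 0.517 TPM ± 0.377, and HOXD11, next to it, from 7.20 TPM ± 0.736 to 0.993 TPM ± 0.445 and 0.298 TPM ± 0.185. Of interferon-stimulated genes, the restriction factor TRIM22 rose from 1.18 TPM ± 0.368 to 16.9 TPM ± 4.39 and 14.1 TPM ± 7.93, while OAS1, USP18 and IFI27 fell in both clones. Of the 26 interferon-stimulated genes 1 rose and 4 fell in clone 1P, and 3 rose and 4 fell in clone 3.3, and the list was called in neither (adjusted p = 0.303 and 0.945). Each gene named here was called in both clones on TPM and on scaled TPM.

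Between 12 and 23 Mb on chromosome 9, 36 of 36 genes with a mean of at least 1 TPM lay below the median gene in both clones, with a median relative log2 fold change of -1.94 and -1.97. From 26 to 36 Mb, 36 of 68 did, with medians of -0.11 and -0.10.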
